A study of Mus musculus with 8 samples.

How the data were processed

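The series holds single-cell RNA-seq libraries of mouse liver endothelial cells that were isolated by fluorescence-activated sorting and run on the 10x Genomics Chromium platform, in which each captured molecule carries a unique molecular identifier (UMI). The markers used in the sort are not given in the sources used here. There are 8 libraries, 1 per stage: embryonic days 12, 14, 16 and 18 form the fetal group and postnatal days 2, 8, 15 and 30 form the postnatal group, and libraries are named by stage below (E12 to P30). The labels do not say how many animals went into a library, and no stage has a second library, so the spread within a group includes the differences between its stages and p-values measure only the spread between these libraries.

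The authors deposited UMI counts per gene and barcode as 1 matrix per library, with gene symbols and no further normalisation. Per the submitters' processing notes, reads went through FastQC 0.11.3, Cell Ranger 4.0.0 and Seurat 3.2.2 and 3.2.3 with the mm10 build; the annotation release they counted against is not given in the sources used here. The authors also deposited a table of the cells they kept, with its UMI count and gene count per cell, a percent of mitochondrial UMIs, a cluster code and an experimental batch for each cell. The deposited cluster codes and batch letters are entries of another kind than measurements and were used only to group cells and libraries. The deposited cell cycle score columns and the deposited UMAP coordinates were not used here. The matrices held 32285 genes in every library. The values showed that the cells kept had at least 200 and under 5000 genes and under 20% mitochondrial UMIs, over genes found in at least 3 barcodes, with the exception of 1 cell in each of E14, E16 and P15. The tables held between 4640 (P30) and 9404 (E12) barcodes, and the authors kept between 3986 (P30) and 7054 (E12) of them.

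The 26 deposited clusters carry codes that no source used here explains, so each was named from marker genes fixed before the data were examined, using its 10 genes of highest fold against the other clusters and its level of pan-endothelial markers. Clusters with an endothelial marker level of at least 0.25 of the highest cluster, and without a majority of another type's markers, were taken as endothelial (17 clusters). A cluster that mixed endothelial with macrophage genes was left out of the endothelial cells, and 1 cluster led by histone genes and Slc6a4 was left unnamed. Among the endothelial clusters, 3 were led by cell cycle genes, 1 by arterial-like genes (Gja5, Gja4) and 1 by venous-like genes (Rspo3, Nts, Edn1). A narrower class of 11 sinusoidal-like clusters was chosen after the data were seen, from sinusoidal marker levels of at least 0.1 of the highest cluster and without the venous-like, arterial-like and cycling clusters, and serves as an alternative only. Doublets were not removed in the main analysis. Scrublet's own threshold marked under 0.5% of the cells in every library other than E14 (0.867%), so a second alternative removed the cells of highest doublet score at a rate that grows with the number of cells in the library.

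UMI counts were summed over the endothelial cells of each library. Those sums ran from 24133814 UMIs in 3936 cells (P30) to 65845266 UMIs in 5840 cells (E12), and the median UMIs per endothelial cell fell from 11301.5 at E12 to 5739.5 at P30, with 5356 at P15 as the lowest. Levels are given as CPM, each count relative to the library's endothelial UMIs. Gene tests used the quasi-likelihood F test of edgeR 4.0.16 (limma 3.58.1, R 4.3.3) on the summed counts, with TMM normalisation, the filterByExpr filter, a two-sided Benjamini-Hochberg adjusted p under 0.05 and all 8 libraries in each fit. The tests were fetal against postnatal (13741 genes tested), a slope over stage order from 1 to 8 (14115 genes), and a model with separate fetal and postnatal slopes, whose difference was tested too (14536 genes, 4 residual degrees of freedom). Standard errors (SE) of log2 changes were taken as the size of the change divided by the square root of F, and n is 4 libraries per group for fetal against postnatal and 8 libraries for the stage trend. A gene with 0 counts in a library is given as CPM, with the limit of 3 counts, since its fitted change depends on the prior count. Exact Poisson and exact (Clopper-Pearson) binomial 95% intervals cover counting error only.

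For zonation, cells were thinned to 3000 UMIs, the largest of 5 preset depths that kept at least 80% of the endothelial cells of every library; between 82.2% (P30) and 96.3% (P2) remained. A score was the mean log level of Wnt2, Rspo3, Thbd and Cdh13 (pericentral) minus that of Dll4, Efnb2, Msr1 and Ltbp4 (periportal). Opposition is the correlation over cells between all pericentral and all periportal landmarks. The held-out value is the log2 ratio of the summed level of 8 further pericentral landmarks between cells scoring above 0 and below 0, minus the same ratio for 8 further periportal landmarks. Counts summed per library and side of the score were tested in edgeR with the library as a block and the score genes left out (12147 genes).

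Gene lists (27) and lists of cell type markers (16) were fixed before the data were examined, as were the tests, the alternatives listed as planned and the rule for named genes. The lists with at least 3 tested genes (39) were compared between periods with camera (limma, preset correlation 0.01), and beside it with an estimated correlation and with fry. The named genes are the 8 highest and 8 lowest log2 changes (5 and 5 for the slopes) among genes past the threshold with a mean of at least 20 CPM and, for the fetal against postnatal test, no overlap between the groups. Gene models without a proper name, mitochondrially encoded genes, haemoglobins and markers of other cell types were left out of that rule, and Maf and up to 4 members of each list with the smallest adjusted p were added. A result for 1 gene that the rule names is not reported here. Genes of near-identical families (H2-Q6 and H2-Q7, Ifi203 and Mndal, Hba-a1 and Hba-a2) may share reads, so their separate levels are uncertain. Positions are from GENCODE vM21 on GRCm38, the assembly that mm10 names, matched by symbol. Steps between neighbouring stages have no test: a list's median step is placed among 10000 random lists of the same size matched on expression.

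The tests were tested on simulated counts drawn from the library means with 200 changed genes. The fetal against postnatal test recovered 28% of genes changed by 1 on the log2 scale and 100% of those changed by 2 (13906 genes tested). The stage trend recovered 83% at 0.25 and 100% at 0.5 per stage (14114 genes). Of the separate slopes only the postnatal one was given changed genes. Its test recovered 10% at 0.25 and 77% at 0.5, and that of the difference of slopes 16% at 0.5 (14333 genes). The zonation test of postnatal libraries recovered 95% at 0.5 and the test of the difference 49% at 0.5 (11752 genes). Unchanged genes were called in at most 0.0952% of cases. These rates hold for the simulated setting, and not for libraries with stage trends and a spread that differs between genes.

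The batch column puts E12 and E18 in 1 batch, E14 and E16 in another, P8 and P15 in another, and P2 and P30 in batches of their own. No batch holds libraries of both periods, so period and batch cannot be told apart. Alternatives changed 1 choice at a time: size factors, DESeq2 1.42.0, no filter on low counts, each library left out, all barcodes, thinned cells, equal numbers of cells (2525 per library), removal of doublets at Scrublet's own threshold, log2 days of age, the score landmarks alone and cells at the extremes of the score. Those added after the data were seen were removal of the cells of highest doublet score, no cycling clusters, sinusoidal-like clusters, batch terms, voom, held-out landmarks alone and landmarks thinned alike. Other scalings moved the median log2 change between periods from 0.02 (TMM) to -0.00 (DESeq2 size factors) or 0.20 (none). The remaining steps used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5 and matplotlib 3.10.9.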

Results

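Endothelial cells of the mouse liver line its vessels, and those of the sinusoids form the fenestrated capillaries between the portal tracts and the central veins. Single-cell libraries of sorted liver endothelial cells were collected at 8 stages, 4 fetal (E12, E14, E16, E18) and 4 postnatal (P2, P8, P15, P30), with 1 library per stage. The tables held 104429831 UMIs at E12, 66485202 at E14, 51733270 at E16, 61016499 at E18, 44544078 at P2, 45224569 at P8, 38991343 at P15 and 27836782 at P30. Counts were summed over 5840, 2525, 4363, 5258, 3740, 5119, 5287 and 3936 endothelial cells in the same order of stages. The summed profiles were closest for P8 and P15 (correlation across genes 0.992) and farthest for E12 and P30 (0.859); genes are not independent replicates. The series title names the transcription factor c-Maf and zonated sinusoids, and the comparisons ask which genes change as the sinusoids mature and when pericentral and periportal genes separate between cells.

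Maf, which encodes c-Maf, lies on chromosome 8 at 115682942 to 115707794 on the minus strand (GRCm38, ENSMUSG00000055435.6). Its level was 490 CPM at E12 (exact Poisson interval 484 to 495), 863 at E14, 1288 at E16, 1537 at E18, 1165 at P2, 1790 at P8, 1808 at P15 and 2319 at P30. It rose with stage by 0.21 ± 0.04 (SE, n = 8) on the log2 scale per stage (edgeR adjusted p = 0.00379). Within the fetal stages the slope was 0.49 ± 0.07 (adjusted p = 0.00355) and within the postnatal stages 0.26 ± 0.07 (adjusted p = 0.0470), and the slopes did not pass the test of their difference (-0.23, adjusted p = 0.198). The postnatal minus fetal difference of 0.60 ± 0.32 did not pass (adjusted p = 0.179, 1044 ± 463 CPM in fetal and 1770 CPM in postnatal libraries, SD, n = 4).

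Clec4g, a C-type lectin of sinusoidal endothelium (chromosome 8, 3707064 to 3720651), went from 6.36 CPM at E12 to 3897 CPM at P30, a slope of 0.96 ± 0.16 per stage. Dnase1l3, a secreted nuclease, rose by 0.80 ± 0.11 per stage, the Fc receptor Fcgr2b (chromosome 1, 170958617 to 170976547) by 1.16 ± 0.22, the mannose receptor Mrc1 by 0.28 ± 0.04, and Bmp2, a regulator of hepatic iron handling, by 0.29 ± 0.04 (adjusted p between 0.000262 and 0.00220). Of 15 scavenger and endocytic receptors tested, 8 rose and 2 fell, 12 when adjusted over the list alone; Lyve1 fell by 0.24 ± 0.09 per stage (adjusted p = 0.0450), and Stab1 gave 0.17 ± 0.07 (adjusted p = 0.0541). Of 15 sinusoidal identity genes, 9 rose and 1 fell (11 over the list alone), and of 8 pericentral landmarks held out of the score 5 rose and none fell. The class I antigen presentation genes rose in 16 of 16 members, H2-D1 by 0.61 ± 0.04 per stage, and interferon response genes in 16 of 28 (17 over the list alone), Gbp2 by 0.73 ± 0.08. Markers of other cell types moved in the same summed counts. Macrophage markers went from 18.5 CPM at E12 to 334 CPM at P2 and 158 CPM at P30 (4 of 11 rose and 1 fell, 5 over the list alone). Hepatocyte markers went from 30.2 CPM at E12 to 483 CPM at P15 and 115 CPM at P30 (4 of 13 rose and 1 fell, 4 over the list alone), and 3 of 8 stellate markers rose.

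The steepest rises over all 8 stages were those of Enpep, which encodes aminopeptidase A (chromosome 3, 129269175 to 129332720), Tpbgl (chromosome 7, 99624082 to 99627103), H2-Q7, Xdh, which encodes xanthine dehydrogenase, and Plscr4. Enpep had 0 of 65845266 UMIs at E12, which allows up to 0.0456 CPM, and 183 CPM at P30. Tpbgl went from 0.0759 CPM at E12 to 414 CPM at P30 (1.64 ± 0.14 per stage). The steepest falls were those of Gap43, a membrane protein of growing axons (chromosome 16, 42248442 to 42340651), Igf2bp1 (chromosome 11, 95957163 to 96005940), Meg3, H19 (chromosome 7, 142575529 to 142578143) and Igf2 (chromosome 7, 142650766 to 142666816). Gap43 went from 404 CPM at E12 to 1.57 CPM at P30 (-1.49 ± 0.17 per stage). Igf2bp1, an RNA-binding protein of fetal tissues, went from 133 CPM at E12 to 0 of 24133814 UMIs at P30, which allows up to 0.124 CPM.

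**Figure D1:**
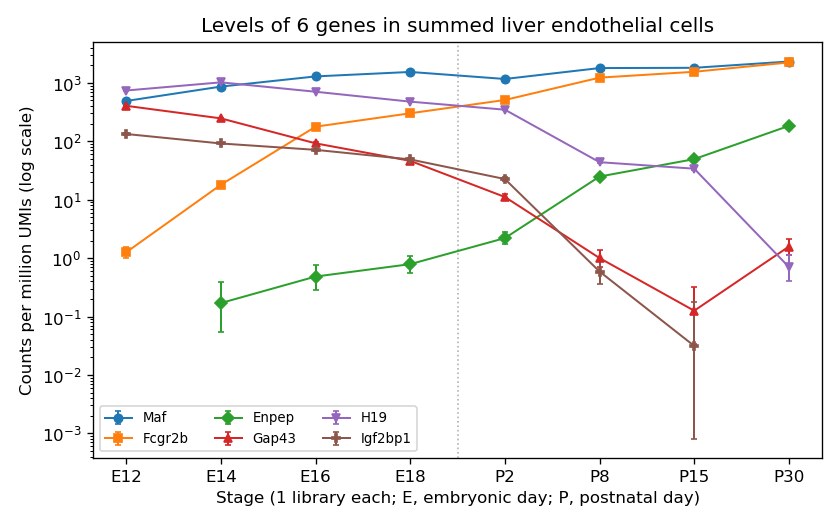
Level of named genes by stage, in CPM of endothelial UMIs on a log axis, 1 library per stage, with exact Poisson intervals for counting error only. Counts of 0 (Enpep at E12, Igf2bp1 at P30) have no point; Maf goes from 490 CPM at E12 to 2319 CPM at P30 and Gap43 from 404 to 1.57 CPM.

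Growth, cell cycle and translation genes fell with stage. Of 19 imprinted growth genes 15 fell and 3 rose (19 over the list alone), and Mest went from 3555 CPM at E12 to 149 CPM at P30 (-0.73 ± 0.08 per stage). All 9 genes tested of the fetal RNA-binding and Lin28 list fell, with Hmga2 at -0.56 ± 0.07 and Lin28b at -1.36 ± 0.14. The S phase genes fell in 33 of 39 members and the G2 and M phase genes in 45 of 52, Rrm2 by 0.45 ± 0.06 and Ccnb1 by 0.65 ± 0.08 per stage in size. The glycolysis genes fell in 13 of 18, the nuclear genes of oxidative phosphorylation in 34 of 39 and the cytosolic ribosomal protein genes in 80 of 83. Slc2a1, which encodes a glucose transporter, had a slope of -0.84 ± 0.13, Cox8a at -0.20 ± 0.02 and Rps26 at -0.33 ± 0.05. Ribosomal protein genes held 227292 CPM at E12 and 82831 CPM at P30. In the same summed counts all 9 erythroid markers fell, with a median slope of -1.27 (193 CPM at E12, 2928 CPM at E14 and 17.9 CPM at P30). All 4 megakaryocyte markers tested fell as well, with a median of -0.74 (408 CPM at E12 and 52.4 CPM at P30), as did 2 of 3 B cell markers. The median slope was -0.52 for the imprinted growth genes, -0.56 for the fetal RNA-binding list and -0.21 for the ribosomal protein genes. In all, edgeR called 8016 of 14115 genes for the stage trend, 4000 rising and 4016 falling, and between 6195 and 8205 with any library left out. With batch as a fixed term 4564 genes passed, 3878 of them called in the same direction without it, and Meg3 (-0.60, adjusted p = 0.220) and Igf2 (-0.18, adjusted p = 0.455) no longer passed. That slope comes only from E12 with E18, E14 with E16 and P8 with P15, because P2 and P30 are batches of their own.

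**Figure D2:**
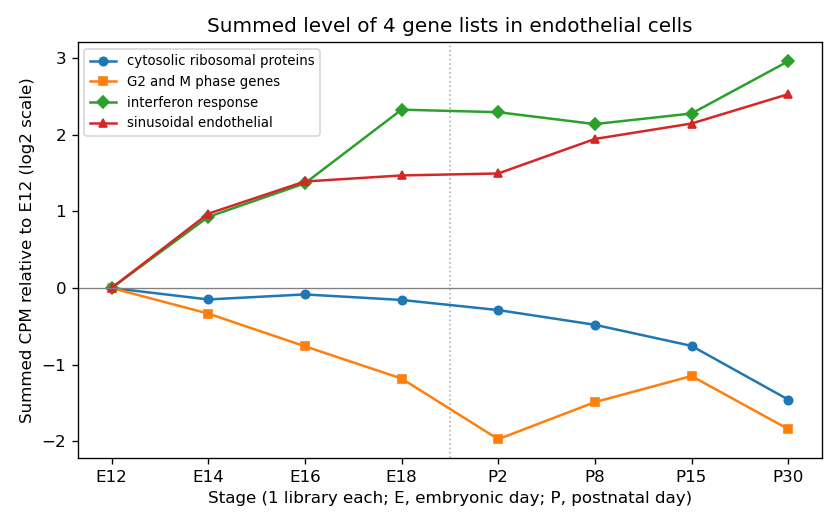
Summed CPM of 4 gene lists by stage on a log2 scale relative to E12, 1 library per stage, without error bars. Ribosomal protein genes go from 227292 CPM at E12 to 82831 CPM at P30 and G2 and M phase genes from 6970 to 1946 CPM, while interferon response genes go from 1324 to 10298 CPM and sinusoidal markers from 3151 to 18191 CPM.

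The steepest genes were not the same in the fetal and postnatal stages, which is not itself a test of a difference. Among the steepest genes below, the difference of slopes passed for Fcgr2b, Ifi44, Mndal, Ifi203, Tnfsf10, Cd34, Plpp2, Igf2bp1, Meg3, Igf2 and Csf2rb2. Between E12 and E18 the steepest rises were those of Fcgr2b (2.65 ± 0.36 per stage) and of the interferon-inducible genes Ifi44, Mndal, Ifi203 and Tnfsf10 (2.40 to 2.62 per stage). The steepest falls were those of Basp1 (-1.19 ± 0.14), Gap43, Cd34 (-1.12 ± 0.05), Cavin3 and Plpp2 (edgeR adjusted p between 0.000653 and 0.0342 for these 10 genes). All 28 interferon response genes rose within the fetal stages, against 3 within the postnatal stages, and 12 passed the test of the difference of slopes (25 over the list alone). Macrophage markers moved with them: 5 of 11 rose in the fetal stages, 3 of 11 fell in the postnatal stages and 6 passed the test of the difference. Neutrophil markers did so too, with 4 of 8 rising in the fetal stages (2.66 CPM at E14 and 27.8 CPM at E18) and 2 of 8 passing the test of the difference (7 over the list alone). Between P2 and P30, H2-Q7 (2.07 ± 0.28), Enpep (1.85 ± 0.24), Xdh, Ltc4s, a leukotriene synthase, and C5ar2 rose most steeply. The stages of this slope leave out E12, where Enpep had 0 counts. Igf2bp1, Meg3 (-2.54 ± 0.34), Igf2 (-2.31 ± 0.15), H19 (-2.25 ± 0.38) and Csf2rb2 (-2.19 ± 0.16) fell most steeply. Igf2bp1 had 22.6, 0.589, 0.0314 and 0 CPM at P2, P8, P15 and P30. Igf2 had 78.7 CPM at P2, 8.99 CPM at P8 and 2.83 CPM at P15. The imprinted growth genes fell in 14 of 19 members within the postnatal stages and the ribosomal protein genes in 66 of 83, against 6 of 19 and 14 of 83 within the fetal stages, and 8 and 17 passed the test of the difference. Megakaryocyte markers fell in 4 of 5 genes before and 2 of 5 after birth. Angiocrine signals rose in 8 of 24 genes before birth, with Wnt2 at 2.16 ± 0.21, Rspo3 at 1.85 ± 0.28 and Hgf at 0.93 ± 0.10 per stage, and 10 of 24 had a lower slope after birth. Rspo3 is a leading gene of the venous-like cluster, which held 0.0856% of endothelial cells at E12, 13.2% at E18, 15.8% at P2 and 0.178% at P30. Venous markers rose in 5 of 7 genes before birth, and 5 of 7 had a lower slope after birth.

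The fetal slope passed for 5440 of 14536 genes (2716 rising, 2724 falling), the postnatal slope for 2567 (1014 rising, 1553 falling) and their difference for 1308 (383 higher and 925 lower after birth). Slopes are per stage, and postnatal stages lie further apart in days than fetal ones. The difference therefore does not compare rates per day, and days of age were fitted for the stage trend only. Without E12 the fetal slope passed for 767 genes and without E18 for 2718. Without P2 the postnatal slope passed for 194 genes and without P30 for 794. The difference passed for 219 genes without E12, 589 without E14, 517 without E16, 200 without E18, 211 without P2 and 823 without P8, and for 2217 with DESeq2. With each fetal library left out in turn Gap43 lost its fetal call (adjusted p from 0.0576 to 0.195), as it did with DESeq2 (adjusted p = 0.137) and with all barcodes (0.115). Without E12 Basp1 (adjusted p = 0.0552) and Cavin3 (log2 slope -0.83) lost theirs, and Cavin3 also without E18 (0.0921). After birth H2-Q7, Xdh and Ltc4s lost theirs without P2 (adjusted p = 0.0807, 0.0711 and 0.106) and without P30 (0.135, 0.0534 and 0.0746), and H19 without P2 (0.204), with all barcodes (0.0715) and in sinusoidal-like clusters alone (0.0571).

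Several genes with steep trends also differed between fetal and postnatal libraries. Enpep was at 0.360 ± 0.348 CPM in the fetal and 65.0 ± 81.3 CPM in the postnatal libraries (SD, n = 4 each). Tpbgl was at 2.53 ± 2.51 and 223 ± 158 CPM, and Cyp26b1, which degrades retinoic acid, at 6.52 ± 5.95 and 156 ± 92.9 CPM (log2 change 4.39 ± 0.79). H2-Q7, Xdh, Plscr4, the chemokine gene Cxcl9 and Fabp1 rose by 4.32 to 6.79. Fabp1, an abundant hepatocyte transcript, was at 1.80 ± 1.83 CPM in the fetal and 39.6 ± 6.13 CPM in the postnatal libraries. Gap43 fell by 6.04 on the log2 scale (197 ± 162 against 3.46 ± 5.15 CPM), Slc2a1 by 3.73 (46.3 ± 26.8 against 3.99 ± 2.35 CPM), and Meg3, Gpx3, Fn1, Col18a1, Ccnb1 and Traf4 by 2.91 to 4.28. The adjusted p of these 16 genes ran from 0.0304 to 0.0479.

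By list, the postnatal libraries were higher in 11 of 16 class I antigen presentation genes (14 over the list alone), among them H2-D1 (154 ± 81.1 CPM in the fetal libraries, log2 change 2.51 ± 0.55) and Psmb10 (1.21 ± 0.30). They were also higher in 5 of 28 interferon response genes (3 over the list alone). Hepatocyte markers (112 ± 61.6 CPM fetal, 309 ± 162 CPM postnatal) and macrophage markers (89.6 ± 68.3 and 234 ± 83.2 CPM) were higher in 4 of 13 and 2 of 11 members in the same libraries. Sinusoidal identity genes were higher in 4 of 15 (Bmp2 1.26 ± 0.29, Plxnc1, Flt4 and Kdr 0.76 ± 0.22). Scavenger receptors were higher in 2 and lower in 1 of 15 (Scarb2 1.71 ± 0.47, Asgr1, a hepatocyte receptor at 1.28 CPM after birth, and Colec12 -2.50 ± 0.40). Held-out pericentral landmarks were higher in 5 of 8 (Kit 2.81 ± 0.58, Rab3b 1.49 ± 0.18) and lysosome genes in 4 of 24 (Psap 0.94 ± 0.24). Clec4g gave 3.22 ± 1.01 (adjusted p = 0.0512) and Fcgr2b 3.33 ± 1.26 (adjusted p = 0.0791). Endothelial transcription factors were higher in 6 and lower in 2 of 32 (Klf4 2.09 ± 0.26, Lyl1 -1.08 ± 0.18), and angiocrine signals higher in 5 and lower in 4 of 24 (Ccn2 -2.30 ± 0.26, Igf1 -2.34 ± 0.52).

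The postnatal libraries were lower in 38 of 52 G2 and M phase genes (45 over the list alone), 21 of 39 S phase genes (29), and 12 of 18 glycolysis genes (12). They were also lower in 22 of 83 ribosomal protein genes (58), 6 of 39 oxidative phosphorylation genes (17), 5 of 9 fetal RNA-binding genes (8) and 5 of 19 imprinted growth genes (9). Examples are Ube2c (-2.42 ± 0.49), Aldoa (-1.56 ± 0.30), Rpl22l1 (-1.71 ± 0.37), Trim71 (-2.65 ± 0.44) and Mest (3355 ± 782 CPM fetal, -2.67 ± 0.57). In the imprinted list Dcn, also a stellate cell marker, rose by 2.79 ± 0.64, and stellate markers were at 6.58 ± 2.24 CPM in the fetal and 20.7 ± 3.73 CPM in the postnatal libraries. Erythroid markers were lower after birth in 8 of 8 genes (1019 ± 1299 against 23.3 ± 12.2 CPM, with 2928 CPM at E14), and megakaryocyte markers in 2 of 4. Matrix genes went both ways (4 higher and 6 lower of 22; Lama5 1.78 ± 0.41, Fn1 -3.48 ± 0.74), and none of 14 Notch pathway genes, 8 held-out periportal landmarks or 5 neutrophil markers passed the edgeR test, over all genes or over the list alone. Of 9 sinusoidal markers none passed over all genes and 3 over the list alone (median log2 change 0.55, 6576 ± 2539 CPM fetal and 13290 ± 3884 CPM postnatal).

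Of 39 lists tested, 22 passed camera with its preset correlation, with the smallest adjusted p for the G2 and M phase genes (2.31e-19, median log2 change -1.54), ribosomal proteins (1.16e-16, -0.76), S phase (3.63e-09, -1.07), class I genes (1.73e-07, 2.15) and glycolysis (2.92e-07, -1.36). With an estimated correlation none passed, and the smallest adjusted p was 0.527, with 1 list at an unadjusted p under 0.05. By fry the smallest adjusted p was 0.0642. Over all genes edgeR called 2974 of 13741 (1480 higher and 1494 lower after birth, and 6034 at an unadjusted p under 0.05), and 2438 of them had no overlap between the groups. Among all tested genes 31.3% had none, against 2.86% by chance in exchangeable libraries. These libraries follow stage order, so a stage trend alone can raise that share. The count hung on single libraries: it was 348 without E12, 0 without E14, 1 without E16, 5140 without E18, 4599 without P2, 0 without P8, 0 without P15 and 55 without P30. At an unadjusted p under 0.05 edgeR still found 4551 genes without E14, 4910 without P8 and 4733 without P15. DESeq2 called 5006 genes with all libraries. Voom called 2988 without a batch term and 6702 with batch as a random block, at a negative estimated correlation within batches (-0.41). No batch holds both periods, so the block cannot separate batch from period.

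Endothelial cells made up 81.6 ± 16.8% of the cells kept in the fetal and 95.7 ± 2.55% in the postnatal libraries (SD, n = 4; exact permutation p = 0.0571), from 57.6% at E14 to 98.7% at P30. Cycling clusters held 30.2% of the endothelial cells at E12 (1763 of 5840; exact Clopper-Pearson interval 29.0 to 31.4%), 14.4% at E14, 14.3% at E16, 10.2% at E18, 4.36% at P2, 5.61% at P8, 8.10% at P15 and 1.80% at P30 (interval 1.41 to 2.27%). Erythroid clusters held 35.3% of the cells at E14 (interval 33.9 to 36.7%), 6.87% at E16, 2.06% at E18, 1.16% at E12 and 0.0753 to 0.445% after birth. Cycling cells were 17.3 ± 8.83% before and 4.97 ± 2.62% after birth, a difference of -12.3 points (exact permutation p = 0.0286, the smallest that 8 libraries allow, and 0.114 after adjustment over 12 classes). The difference for erythroid cells was -11.1 points (same exact p) and -3.15 points without E14, that for cycling cells -8.00 points without E12, and that for endothelial cells 14.1 points and 6.12 points without E14. Over the 8 stages the cycling share had a Spearman rho of -0.905 (exact permutation p = 0.00456, adjusted over 12 classes 0.0183) and Pearson r of -0.856 (exact p = 0.00193, adjusted 0.0116), and r was -0.794 without E12 and P30. Within the 3 batches of 2 stages the cycling share went from 30.2% (E12) to 10.2% (E18), from 14.4% (E14) to 14.3% (E16) and, against the trend, from 5.61% (P8) to 8.10% (P15). No batch holds both periods, and the sort and the cells loaded can set these shares.

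**Figure D3:**
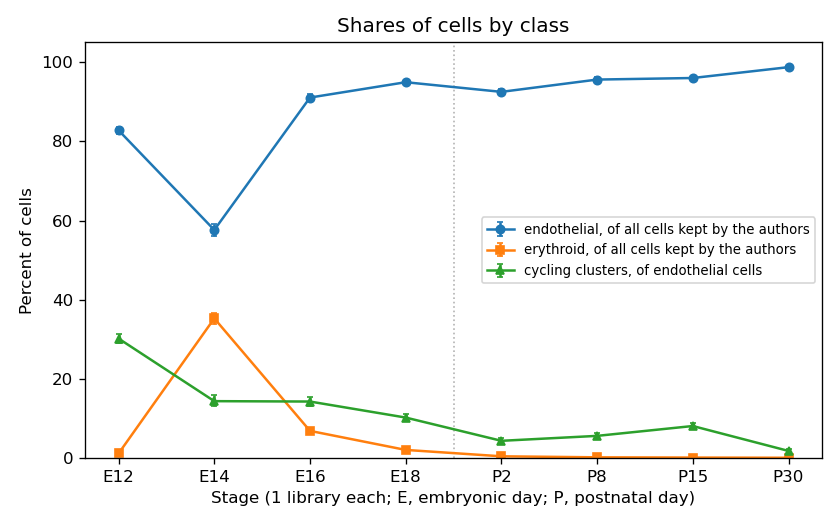
Share of cells by stage in percent, 1 library per stage, with exact Clopper-Pearson intervals for counting error only. Endothelial and erythroid cells are shares of all cells kept, and cycling cells shares of endothelial cells; cycling cells go from 30.2% at E12 to 1.80% at P30, and erythroid cells peak at 35.3% at E14.

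In cells thinned to the same depth, pericentral and periportal landmarks opposed each other more at later stages. The correlation over cells was -0.0763 at E12, -0.162 at E14, -0.292 at E16, -0.352 at E18, -0.468 at P2, -0.392 at P8, -0.374 at P15 and -0.512 at P30. The mean was -0.221 ± 0.125 in the fetal and -0.437 ± 0.0647 in the postnatal libraries (SD, n = 4; exact permutation p = 0.0286, the smallest possible, and 0.0571 adjusted over 2 zonation measures). Against stage order Spearman's rho was -0.905 (exact permutation p = 0.00456, adjusted 0.00913) and Pearson's r -0.894 (exact p = 0.00273, adjusted 0.00546), with r at -0.757 without E12 and P30. With all UMIs of each cell the difference between periods was -0.206 (exact p = 0.0857) and rho -0.714 (exact p = 0.0576), with r at -0.767 (exact p = 0.0255). For held-out landmarks alone they were -0.0940 (exact p = 0.171) and -0.571 (exact p = 0.151), with r at -0.730 (exact p = 0.0368). With every landmark thinned to its lowest level over the libraries they were -0.0509 (exact p = 0.286) and -0.333 (exact p = 0.428), with r at -0.503 (exact p = 0.205). The held-out separation sums UMIs over genes, so Fabp4 weighs most on the pericentral side (91069 UMIs at E18, against 2549 for Lgals1). On the periportal side Adam23 had 118 UMIs at E12 and 4603 at P30, and Sox17 1756 and 1040. Of 5360 cells at E12, 243 scored above 0 and 1642 below, against 165 and 877 of 2368 at E14. At P30 these counts were 1291 and 1693 of 3235. Cells that scored 0 were on neither side, so the earliest values rest on few pericentral-side cells. The held-out landmarks separated by 0.0714 at E12, 1.56 at E14, 2.05 at E16, 2.14 at E18, 2.74 at P2, 1.78 at P8, 1.56 at P15 and 1.96 at P30 on the log2 scale. Their means of 1.45 ± 0.957 and 2.01 ± 0.512 differed by 0.555 (exact permutation p = 0.457), and by 0.0937 without E12. Against stage order rho was 0.214 (exact p = 0.619) and r 0.493 (exact p = 0.215), with r at -0.0235 without E12 and P30. With all UMIs the difference was 0.678 (exact p = 0.343), rho 0.429 (exact p = 0.299) and r 0.558 (exact p = 0.143). Between the highest- and lowest-scoring 33.3% of cells they were 1.02 (exact p = 0.0571), 0.762 (exact p = 0.0368) and 0.709 (exact p = 0.0448), with r at 0.444 without E12 and P30. At E12 each 33.3% held 1786 cells, so both included cells that scored 0, taken at random. In sinusoidal-like clusters the difference, rho and r were 0.955 (exact p = 0.0286), 0.905 (exact p = 0.00456) and 0.898 (exact p = 0.00149). There 96 of 3057 cells at E12 scored above 0. Within batches the correlation went from -0.0763 (E12) to -0.352 (E18), from -0.162 (E14) to -0.292 (E16) and, against the trend, from -0.392 (P8) to -0.374 (P15), and no batch holds both periods.

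**Figure D4:**
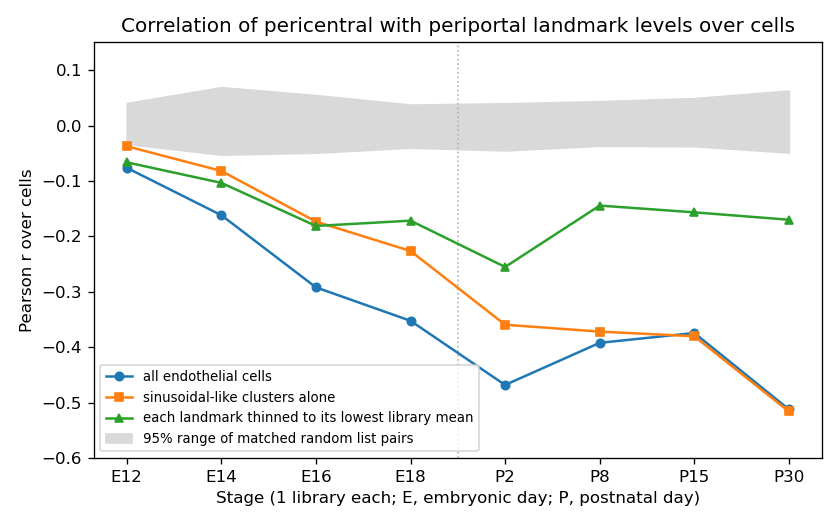
Correlation over cells between pericentral and periportal landmark levels by stage, 1 library per stage, in all endothelial cells, in sinusoidal-like clusters alone and with each landmark thinned to its lowest library mean; the grey band holds 95% of matched random list pairs. In all endothelial cells the correlation is -0.0763 at E12 and -0.512 at P30, and with landmarks thinned alike it is -0.0664 and -0.170.

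Cells on the pericentral side of the score were higher in Nts, which encodes neurotensin (chromosome 10, 102481756 to 102490486), by 4.42 ± 0.44 in the fetal and 3.92 ± 0.41 in the postnatal libraries, and in Lhx6 (chromosome 2, 36081953 to 36105408) by 4.02 ± 0.30 and 3.32 ± 0.22. Fbln2, Samd5 and Ackr3, a scavenging chemokine receptor, were higher on that side in both periods. Trib2 and Dnah8 were among the 8 highest before birth, and Aplnr, Rnf165 and Edn1 after birth. On the periportal side Gja5, the gap junction gene of connexin 40 (chromosome 3, 96904693 to 97077416), was higher in both periods (-2.98 ± 0.28 and -3.35 ± 0.34), as were Vegfc, Mecom, Igf2 and H19. Cxcl9, Adam23 and Plac8 were among the 8 lowest before birth and Atp13a3, Col18a1 and Cavin3 after birth. Nts, Lhx6, Fbln2, Samd5 and Edn1 are among the leading genes of the venous-like cluster, and Gja5, Mecom, Atp13a3, Col18a1 and Plac8 among those of the arterial-like cluster. In the sinusoidal-like clusters alone Nts (3.36 and 2.68) and Lhx6 (2.44 and 2.89) still passed, and Gja5 did not (0.28 before birth, adjusted p = 0.918, and -0.96 after, adjusted p = 0.699), nor did Atp13a3 (0.29, adjusted p = 0.683) and Cavin3 (-1.13, adjusted p = 0.108) after birth. Without E18, Cxcl9 (adjusted p = 0.643) and Dnah8 (log2 difference 1.49) lost their fetal call, as did Cxcl9 between the highest- and lowest-scoring 33.3% of cells (0.369). Without P2, Igf2 (0.756), Cavin3 (0.0525) and H19 (0.557) lost their postnatal call. Maf was higher on the periportal side by -0.56 ± 0.08 (edgeR adjusted p = 0.000167) before and -0.30 ± 0.08 (adjusted p = 0.0152) after birth.

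Among landmarks held out of the score, Wnt9b (4.93 and 3.89 in fetal and postnatal libraries), Ramp3 (1.49 and 1.75), Ptgs1 (0.87 and 0.80) and Fabp4 (0.46 and 0.93) were higher on the pericentral side in both periods, and Ntn4 (-1.39 and -1.35) and Efna1 (-1.13 and -0.91) on the periportal side. Kit and Lgals1 passed after birth (0.84 and 0.96) and not before (0.52, adjusted p = 0.0723, and 0.40, adjusted p = 0.0825), a difference between periods that did not pass for either gene (0.32, adjusted p = 0.826, and 0.56, adjusted p = 0.462). Rab3b gave -0.44 (adjusted p = 0.125) before and 0.60 after birth, and its difference of 1.04 passed (adjusted p = 0.0327). In all, edgeR called 1145 of 12147 genes along the score in the fetal libraries (500 pericentral, 645 periportal) and 1110 in the postnatal libraries (550 and 560), and 13 for the difference. In sinusoidal-like clusters alone the fetal count was 408, and 354 of these genes were called in the same direction in all endothelial cells (30.9% of the 1145). Between the highest- and lowest-scoring 33.3% of cells it was 744, with 487 in common (42.5%). Under the same 2 settings the difference passed for 39 and 30 genes, of which 2 and 1 were among the 13, and without a filter on low counts for 124, with all 13 among them. The fetal count was 602 without E16 and 331 without E18, and the postnatal count 550 without P2 and 699 without P8. The difference passed for 32 genes without E12, 7 without E14, 2 without E18, 89 without P2, 5 without P8, 7 without P15 and 5 without P30.

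Between neighbouring stages, with no replicate check, the interferon response genes had a median log2 step of 1.92 from E16 to E18, -0.57 from E18 to P2 and 1.19 from P15 to P30 (100th, 0th and 100th percentile of 10000 random lists). Each of these steps is also a change of batch, and only those from E14 to E16 and from P8 to P15 lie within a batch. The class I genes stepped by 1.01 from E12 to E14 and by 1.38 from P15 to P30. The pericentral score landmarks stepped by 1.93 from E14 to E16, and scavenger receptors by 1.07 from E12 to E14 (both at the 100th percentile). The G2 and M phase genes stepped by -1.32 from E18 to P2 and by 0.78 from P2 to P8. The glycolysis genes stepped by -0.93 from E12 to E14 and the imprinted genes by -0.96 from P2 to P8. Maf stepped by 0.82, 0.58, 0.25, -0.40, 0.62, 0.01 and 0.36 from stage to stage, and the interval of the P8 to P15 step includes 0 (-0.00 with TMM-scaled library sizes). Of 259 steps of lists, 158 lay outside 95% of the random lists.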

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

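The tests of the stage trend within batches and of the sinusoidal-like clusters were chosen after the results were seen, and the landmark test went from 1 draw to 20 after its first draw was seen.

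Gene levels differed between fetal and postnatal libraries and followed stage order. Of 35 splits of the 8 libraries into 4 and 4, only 1, the real one, called as many genes (2974), and the highest of the others called 0. The libraries are not exchangeable, because 8016 of 14115 genes followed stage order and every other split mixes earlier with later stages. The splits therefore cannot tell a difference between periods from a stage trend. The 3 splits that keep every batch whole are too few to exclude chance for batches. The count for fetal against postnatal was 348 without E12, 0 without E14, 1 without E16, 5140 without E18, 4599 without P2, 0 without P8 or P15 and 55 without P30 by edgeR (4551, 4910 and 4733 genes at an unadjusted p under 0.05 without E14, P8 and P15). Without cycling clusters 69.9% of the genes (Wilson interval 68.3 to 71.6%) were called in the same direction. Such intervals treat genes as independent, which they are not, and leave out the spread between libraries. The share of 69.9% argues against the cells of the cycling clusters as the whole cause. Cycling cells outside them stay open, because G2 and M phase genes still fell with stage there in 45 of 52 members. Their median slope was -0.495 without those clusters and -0.328 with them. The 67.6% (65.8 to 69.2%) called with cells thinned to a fixed number of UMIs leave UMIs per cell open, because thinning keeps the expected composition of the sums. The number of batches with libraries of both periods was 0, so batch and period cannot be told apart, whereas genes called for the trend without a batch moved in their direction within it in at least 64.5% of cases, which argues against batch as the whole cause of the trend. With batch as a fixed term 3878 of 8016 trend genes (48.4%) were called in the same direction, and 96.2% kept their sign. That fit draws its slope only from E12 with E18, E14 with E16 and P8 with P15, and has fewer residual degrees of freedom. The lost calls therefore cannot tell batch from lost power, and batch stays open as a part of the cause. The difference may follow development, as a hypothesis, with UMIs per cell, cycling cells outside the cycling clusters, batch and differences between litters or animals left open.

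The ribosomal protein genes fell with stage, with a median slope of -0.21 per stage over 83 genes. Without cycling clusters it was -0.212, which argues against the cells of those clusters as its cause. Cycling cells outside them stay open, because G2 and M phase genes still fell there, with a median slope of -0.495. In cells thinned to a fixed number of UMIs the median slope of the ribosomal protein genes was -0.203. Thinning keeps the expected composition within each cell, so UMIs per cell stay open. Batch stays open too, because P30, the library with the lowest ribosomal level (82831 CPM), is a batch of its own. A change of translation with age may account for the fall, as a hypothesis that was not tested.

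Pericentral and periportal landmarks opposed each other more at later stages in cells thinned to the same depth. In the sinusoidal-like clusters alone the Spearman correlation of this measure with stage order was -1. That argues against venous-like and arterial-like clusters as the whole source of the change with stage. The correlation over cells there was -0.0374 at E12 and -0.226 at E18, against -0.0763 and -0.352 in all endothelial cells. At P30 it was -0.516 against -0.512. Clusters outside the sinusoidal-like class therefore held part of the fetal opposition. With every landmark thinned to its lowest library mean the correlation at P30 was below that at E12 by -0.104 (SE 0.0218), too close to the bound of 0.1 set beforehand to tell, and rho with stage order was -0.333 (exact permutation p = 0.428), so low landmark levels at early stages could account for part of it. Wnt2, a pericentral landmark of the score, had 25 UMIs in the 5360 thinned cells of E12. Maturing zonation, batch and landmark levels stay open.

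Several values stood apart from the other 3 libraries of their period, as 12 of 131 groups tested did. Chance gives about 5% in like libraries, but these follow stage order and many genes were named for steep changes, so that share does not apply. Erythroid cells were 35.3% of the cells at E14. H2-Q7 was highest at E18 among fetal libraries (1.16 CPM) and at P30 among postnatal ones (217 CPM). Ifi44 and Fbln2 were both at 124 CPM at E18. At P2 Gap43 (11.1 CPM), Igf2bp1 (22.6 CPM), H19 (347 CPM), Igf2 (78.7 CPM) and Ackr3 (90.2 CPM) stood above the later postnatal libraries. The median UMIs per cell kept were highest at P2 among postnatal libraries (8795), and the median mitochondrial percent lowest at E12 among fetal ones (6.20%).

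Slopes per stage differed between the periods by a test of the difference for 1308 genes (219 without E12, 589 without E14, 517 without E16, 200 without E18, 211 without P2 and 823 without P8). Postnatal stages lie further apart in days than fetal ones, so these are not differences in rate per day. Of 35 splits 1, the real one, gave as many, with 496 as the highest of the others. The libraries are ordered by stage and not exchangeable, so the splits cannot exclude chance. The 3 splits that keep every batch whole are too few to exclude it for batches. The postnatal slope was lower than the fetal slope for Fcgr2b (-2.01), Ifi44 (-2.29), Mndal (-1.90), Ifi203 (-1.82), Tnfsf10 (-1.81), Plpp2 (-0.59), Igf2bp1 (-4.61, with 0 counts at P30), Meg3 (-2.12), Igf2 (-2.24) and Csf2rb2 (-3.17), and higher for Cd34 (0.66), with edgeR adjusted p from 3.84e-05 to 0.0371.

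Zonation differed between the periods for 13 genes (32 without E12, 7 without E14, 2 without E18, 89 without P2, 5 without P8, 7 without P15 and 5 without P30). Of 35 splits 5 gave as many, and the highest of the others gave 323, so chance in the grouping cannot be excluded. That split points to a structure of the libraries other than period or to an unstable estimate of their spread, and which of these holds was not tested. The postnatal minus fetal differences along the score were -2.38 for Igfbp5, -1.36 for Inhbb, -1.06 for Ednrb, -2.89 for Emp1, -0.996 for Cdh4, -1.85 for Pde7b, -2.34 for Fhdc1, 0.75 for Btnl9, -3.99 for Hspb1, 0.62 for Nid2, 1.04 for Rab3b, 0.97 for Depp1 and -1.04 for Mgst1 (edgeR adjusted p from 0.000114 to 0.0496). For gene lists, 4 of 35 splits gave at least as many lists as the real 22, and the highest of the others gave 24, so chance in the grouping cannot be excluded.

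Barcodes over the upper limit on genes, which the authors left out, held cell cycle genes at 11093 CPM at E12, 12754 at E14, 13588 at E16, 11830 at E18, 6308 at P2, 3895 at P8, 4922 at P15 and 4065 at P30. In the endothelial cells kept these genes were at 9508, 7606, 5692, 4382, 3011, 3636, 4636 and 3061 CPM in the same order.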

How the results depend on the processing

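The alternatives without cycling clusters, with sinusoidal-like clusters alone, with batch terms, with voom, without the cells of highest doublet score, with held-out landmarks alone and with landmarks thinned alike were chosen after the data were seen. No paired analysis was possible because the labels give no replicate numbers that pair fetal with postnatal libraries; the zonation tests compare cells of the same library and have the library as a block. Where a value moved, the cause was not tested. Depth limits genes below the level that 3 counts give, from 0.0456 CPM at E12 to 0.124 CPM at P30.

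Leaving out 1 library gave 0 to 5140 genes for fetal against postnatal (0 without E14, P8 or P15, with 4551, 4910 and 4733 at an unadjusted p under 0.05 in edgeR) and 6195 to 8205 for the stage trend. It gave 767 to 5898 for the fetal slope, 194 to 2591 for the postnatal slope, 200 to 1173 for the slope difference. For zonation it gave 331 to 1583 and 550 to 1426 in fetal and postnatal libraries, and 2 to 89 for the difference, and for lists 15 to 24. It gave differences of -0.260 to -0.168 for the opposition of landmarks, 0.0937 to 0.784 for held-out landmarks, 6.12 to 18.6 points for endothelial cells, -14.6 to -8.00 for cycling cells and -14.5 to -3.15 for erythroid cells.

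DESeq2 called 5006 genes for fetal against postnatal (2969 shared) and 2217 for the slope difference. Voom with batch as a random block called 6702 genes at an estimated correlation within batches of -0.41. Voom without the block called 2988, and the block cannot separate batch from period because no batch holds both. With batch as a fixed term the trend passed for 4564 genes. Comparing the highest- and lowest-scoring 33.3% of cells gave 744 genes for fetal zonation and 30 for the difference, sinusoidal-like clusters gave 408 and 39, and no filter on low counts gave 124 for the difference. With an estimated correlation camera called 0 lists (1 at an unadjusted p under 0.05).

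The difference between periods in the opposition of landmarks was -0.206 with all UMIs (exact p = 0.0857), -0.0940 for held-out landmarks alone (exact p = 0.171) and -0.0509 with landmarks thinned alike (exact p = 0.286). The difference between periods in held-out separation was 0.955 in sinusoidal-like clusters (exact p = 0.0286). In those clusters Gja5 (0.276, fetal) and Atp13a3 (0.291, postnatal) changed sign along the score and did not pass. Over all alternatives the named genes of the trend kept direction and call in 188 results and lost the call in 2. The other totals were 161 and 9 for each of the slopes, 187 and 4 for fetal zonation and 186 and 5 for postnatal zonation. For fetal against postnatal, 2356 results were the same, 683 lost the call, 116 gained one, and 7 changed sign in genes that had not passed.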

Other observations

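The counts of genes in this part come from tests that were planned before the data were examined.

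Other endothelial lists moved in part. Of 20 pan-endothelial and continuous capillary genes 10 rose and 5 fell with stage (16 adjusted over the list alone), and 3 were higher and 1 lower after birth (8 over the list alone). Of 8 endothelial markers 6 rose with stage, of 9 sinusoidal markers 6 rose and 1 fell, of 9 arterial markers 1 rose and 4 fell, of 7 venous markers 3 rose and of 4 lymphatic markers 3 rose. Venous markers stepped by a median of 0.91 on the log2 scale from E16 to E18, -0.76 from P2 to P8 and -1.12 from P8 to P15. Lymphatic markers stepped by 1.63 from P15 to P30. After birth 2 of 7 venous, 1 of 4 lymphatic and 3 of 8 endothelial markers were higher, and 1 of 9 arterial markers was higher and 1 lower. Of 32 endothelial transcription factors 12 rose and 5 fell with stage, and of 14 Notch pathway genes 5 rose and 3 fell.

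Metabolic and transport lists went both ways with stage. Of 19 genes of lipid uptake and fatty acid handling 7 rose and 2 fell, with Mgll, a lipase of monoacylglycerols, at 0.54 and Fabp5, a fatty acid carrier, at -0.41 per stage. Of 24 lysosome genes 14 rose and 2 fell, with Lgmn at 0.42. Of 18 genes of iron handling and BMP signalling 7 rose and 4 fell, and 5 were higher and 1 lower after birth. Of 13 coagulation genes 4 rose and 3 fell, of 22 matrix genes 9 rose and 6 fell. Of 14 hypoxia genes 1 rose and 3 fell (2 lower after birth), of 24 immediate early and stress genes 2 rose and 7 fell, and of 6 class II genes 2 rose. Of 4 pericentral and 4 periportal score landmarks 3 and 2 rose, and of 8 held-out periportal landmarks 2 rose and 3 fell.

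Markers of other cell types also moved in the summed endothelial counts. With stage 4 of 13 hepatocyte markers rose and 1 fell, 9 of 9 erythroid and 4 of 4 megakaryocyte markers fell. Of the others, 4 of 11 macrophage markers rose and 1 fell, 3 of 8 stellate markers rose, 2 of 3 B cell markers fell, 1 of 3 cholangiocyte markers rose and the 1 mesothelial marker tested fell. None of 6 neutrophil markers passed by edgeR, and 1 of 5 general haematopoietic markers rose and 1 fell. T and NK cell markers were at 0.239 ± 0.0988 CPM in the fetal and 0.0928 ± 0.0433 CPM in the postnatal libraries (SD, n = 4), too low to test.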
